A study of Arabidopsis thaliana with 12 samples.

How the data were processed

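Arrays of total RNA from 12 samples of wild-type Arabidopsis, 6 in water and 6 after 3 h in MS with 60 mM sucrose, were analysed. The authors deposited 1 value per probe and array as a spot intensity on a linear scale, with no negative value, exact zeros and a highest value of 100. How the spots were read, corrected for background or scaled is not given in the sources used here, so the unit was judged from the values, and a value of 0 cannot be read as absence of the transcript. A value at the top of the scale is a lower bound, and 9 probes had it on at least 1 array.

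Groups and replicate numbers were taken from the labels. GEO's annotation of the platform, which can be out of date, paired 692 of the 3439 probes with 1 gene (691 genes) and 870 with several, and it did not list the other 1877, which stay unnamed here. No gene was named from a probe with several. Names were updated through the gene ID with a reference table of assembly TAIR10.1, which held 690 of the 692 probes' genes and was used for names alone. The genome build behind the probes is not given in the sources used here, and no coordinates were used. What named genes are known to do is background knowledge, not a result.

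Each array was scaled to the common median, values under the floor of 0.0531 (the 5th percentile of the positive scaled intensities) were set to it, log2 was taken and the arrays were quantile normalized. On an array, between 15.8% and 18.4% of the probes were at the floor, 340 probes on all 12 arrays, and 2407 probes were above it on all 12. Differences are log2 sucrose minus water from limma 3.58.1 (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. They are on the floored scale, which understates the change of dim probes. Group means and SDs are of the deposited intensity, so their ratio can differ from the fold, which comes from the normalized values. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

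The named genes were set before the data were examined: the 10 largest rises and 10 largest falls past the threshold among probes with 1 gene, with the brightest probe of a gene, and up to 4 members of each of 18 gene lists, with the smallest p. Lists needed 5 measured genes for limma's camera test with a preset correlation of 0.01, which none reached. Of these lists, 16 were given by locus and 2 by a rule on annotation text, which matched no gene.

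The labels number the arrays 1 to 6 in both groups without saying that a number pairs them. The deviations of same-numbered arrays from their group means correlated across probes at 0.43, 0.33, 0.27, 0.25, 0.21 and 0.19 for numbers 1 to 6, and each array correlated best with its own number in the other group. By the rule set beforehand, a correlation over 0.1 in every pair, the numbers were taken to pair the arrays, and a fit with the number as a block was set beside the main one. Adjusted p-values of single genes are from the main fit, without this block, unless another fit is named. Within a group, arrays of numbers 1 and 2, 3 and 4, and 5 and 6 resembled each other most, with Spearman correlations across probes of 0.959 to 0.974 in water and 0.942 to 0.948 in sucrose, against 0.933 to 0.961 and 0.847 to 0.923 for other combinations. The labels give no such pairs. A block for any structure that the files showed had been foreseen for the count of called probes, and the pairs that form it were found in the data. Fits with the pairs as a random block, averaged or each alone were added after seeing the data, as was the block for single genes.

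Alternatives chosen before the data were examined were median centring, the values as deposited, cyclic loess, a floor at the 10th percentile, adding 50 instead of a floor, leaving out the dimmest 25% of probes, the replicate block, array weights, a variance trend, a threshold of 0.01 and leaving out each array in turn. The steps were tested on simulated data for this comparison, with 200 of 3439 probes changed by known amounts. The simulated arrays were drawn independently, without a resemblance of consecutive numbers and without a shift that depends on level. The shares called therefore do not cover errors from either. Of the probes changed by 0.5, 1 and 2 on the log2 scale, 22.4%, 61.2% and 83.3% were called, and of the unchanged ones 0.648%.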

Results

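Wild-type Arabidopsis thaliana plants of the ecotype Wassilevskija were compared after 3 h in MS with 60 mM sucrose and after treatment with water. The labels give a time for the sucrose treatment only. Total RNA was measured on 12 arrays, 6 per group, numbered 1 to 6 in both groups, and each array gave an intensity for the same 3439 probes on a scale that ended at 100. The median intensity was 0.177 ± 0.00806 over the water arrays and 0.383 ± 0.0787 over the sucrose arrays (mean of the array medians ± SD, n = 6 each). The sucrose mean was 2.17 times the water mean, and the log2 medians differed (exact permutation test, two-sided, p = 0.00216, the smallest that the 924 splits of 12 arrays can give). Medians went by consecutive array numbers, and with each such pair averaged, 3 against 3, p was 0.10, again the smallest possible. Sucrose arrays 1 and 2 had medians of 0.479 and 0.49, and the other 4 lay between 0.325 and 0.342. The sum over all probes stayed between 3172 and 3461 on every array. Between 13.2% and 15% of the probes were at 0 on a water array and between 10.7% and 12.9% on a sucrose array. No count of reads or molecules underlies such values, so the number of arrays limits the precision. Nothing in the labels says that the 6 arrays of a group came from separate plants, so the p-values measure only the spread between these arrays, which may be technical.

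**Figure D1:**
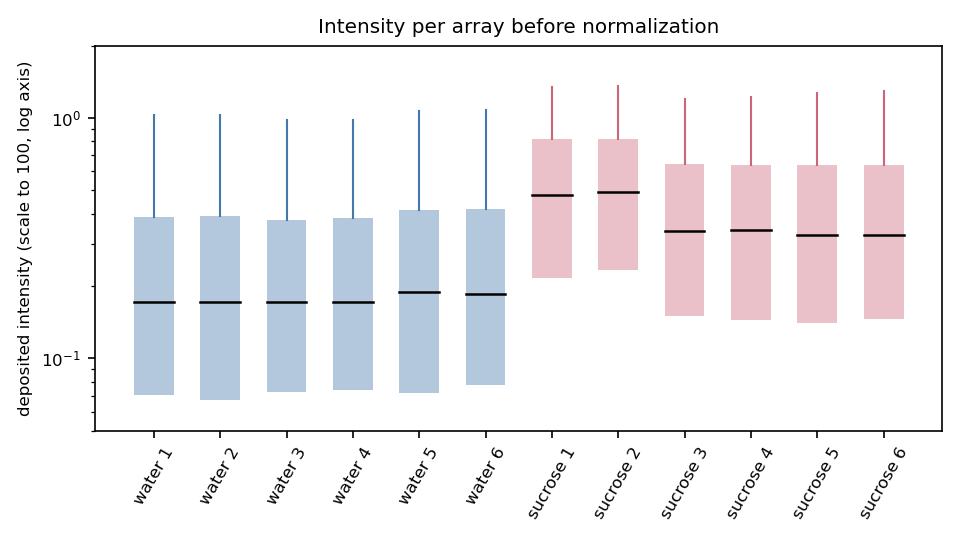
Deposited intensity of each array before any normalization (log axis) in the water group (blue) and the sucrose group (red). The black line is the median over the 3439 probes, the box runs between the quartiles and the thin line reaches the 90th percentile, and all 6 sucrose medians, from 0.325 to 0.49, lie above the 6 water medians, from 0.171 to 0.188.

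The comparison asked which transcripts differed between plants kept for 3 h in MS with sucrose and plants treated with water. No group had MS or sucrose alone, and the labels give no time for water. The differences therefore cannot be assigned to sucrose rather than to MS or treatment time. Throughout, sucrose as the name of a group, array or difference stands for MS with sucrose. AT1G76450, which encodes a PsbP-domain protein of the thylakoid lumen, rose 6.31-fold, and CYN (AT3G23490), which encodes cyanase, fell 8.56-fold. AT4G18180 rose 5.46-fold and AT2G21720 fell 8.58-fold, and these 4 genes passed the threshold under each of the 4 scalings that were run, with sizes that moved with the scaling. Across the array, 1436 of 3439 probes passed a limma adjusted p of 0.05 after quantile normalization, 705 higher and 731 lower in sucrose, and 311 of them were higher and 304 lower by over 2-fold. Among the called probes, 305 belonged to 1 gene, 162 of them higher and 143 lower. The direction of the calls depended on the scaling. Quantile normalization gives all arrays the same distribution, which favours a near-even split, and the median difference over all probes was 0. With the values as deposited, where the median probe was 0.685 higher in sucrose on the log2 scale, 1848 probes were called higher and 227 lower (89.1% higher, against 49.1% after quantile normalization). With median centring alone, 558 were called higher and 1039 lower (34.9% higher). Under all 4 scalings (quantile, cyclic loess, median centring and as deposited), a count made after seeing the data, 514 probes were called higher and 202 lower, of which 119 and 36 belonged to 1 gene. Of the 514 and 202, 271 and 153 also passed with consecutive array numbers averaged, 3 against 3. The 514 and 202 could not exceed the 558 called higher with median centring and the 227 called lower as deposited. Their balance therefore follows partly from the scalings and is no result about direction. Arrays with consecutive numbers resembled each other within both groups. With each such number pair averaged, 3 against 3, an alternative added after seeing the data, 730 probes passed, 716 of them shared with the 1436. Within the number pairs alone, 2 arrays against 2, 1114 probes passed for numbers 1 and 2, 750 for numbers 3 and 4, and 674 for numbers 5 and 6. The difference itself varied between the 3 number pairs for 524 of 3439 probes (limma interaction test, adjusted p under 0.05, with pairs found in the data). Like the counts of 2 against 2, this test takes its error from arrays within a number pair. These may be repeats of the same RNA, so both kinds of count may be too high.

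Among genes with a probe of their own, AT1G76450 had the largest rise after quantile normalization. It went from an intensity of 0.451 ± 0.122 in water to 3.38 ± 0.69 in sucrose (SD, n = 6 each), a log2 difference of 2.66 ± 0.22 (SE, adjusted p = 5.7e-06), or 2.93 as deposited and 1.83 with median centring. AT4G18180 went from 0.11 ± 0.0199 to 1.05 ± 0.138 (log2 2.45 ± 0.14, adjusted p = 4.8e-07), and its difference exceeded that of AT1G76450 as deposited (3.27) and with median centring (2.17). AGL54 (AT5G27090), of the MADS-box family of transcription factors, rose by 2.44 ± 0.36 (adjusted p = 3.1e-04), with 1 water array at the floor. Its difference was 3.83 within numbers 1 and 2, 1.93 within numbers 3 and 4 and 1.56 within numbers 5 and 6. AT3G59300, a pentatricopeptide repeat gene, rose by 2.02 ± 0.21 (adjusted p = 3.1e-05), and AT5G05400, which encodes a disease resistance protein of the NBS-LRR class, by 1.96 ± 0.17 (adjusted p = 9.8e-06, with 1 water array at the floor). The wound-responsive family gene AT4G05070 rose by 2.04 ± 0.51 (adjusted p = 0.0087, with 1 water array at the floor) and AT3G52550 by 2.11 ± 0.45 (adjusted p = 0.0032). With number pairs averaged these last 2 had adjusted p = 0.11 and 0.089, AT4G05070 had 0.056 with array weights, and within numbers 5 and 6 the difference of AT3G52550 was 0.35. The difference of AT4G05070 was 0.47 within numbers 3 and 4 (adjusted p = 0.23) and 1.31 without numbers 1 and 2. LpxA (AT4G29540), which encodes an acyltransferase of the lipid A pathway, rose by 1.90 ± 0.39 (adjusted p = 0.0028) and AT5G52530 by 1.78 ± 0.23 (adjusted p = 1.3e-04). For both of these, 5 of the 6 water arrays were at the floor and 1 was above it, so the floor sets the size of the rise. With a floor at the 10th percentile LpxA was at 1.28 and AT5G52530 at 1.06. With 0.2 added to the scaled value instead of a floor they were at 0.81 and 0.75. AT1G06730, which encodes a pfkB-type carbohydrate kinase, went from 0.502 ± 0.159 to 2.38 ± 0.947 (log2 1.79 ± 0.45, adjusted p = 0.0083), and array 3 lay apart at the low end in both groups. With median centring its difference was 1.07 (adjusted p = 0.065), and with number pairs as a random block its adjusted p was 0.067, whereas the other 9 rises passed under all 4 scalings. Without numbers 1 and 2, AT3G52550, LpxA and AT1G06730 had adjusted p = 0.061, 0.059 and 0.099. For 8 of the 10 genes all 6 sucrose arrays lay above all 6 water arrays, and for LpxA and AT1G06730 5 of 6 did. The genes were picked for their rise on these same arrays, which favours such a separation.

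Among genes with a probe of their own, CYN and AT2G21720 had the largest falls after quantile normalization. CYN went from 8.83 ± 1.68 to 1.1 ± 0.131 (SD, n = 6 each), a log2 difference of -3.10 ± 0.11 (adjusted p = 3.6e-08) that was -4.08 with median centring. AT2G21720 went from 1.22 ± 0.243 to 0.253 ± 0.106 (-3.10 ± 0.26, adjusted p = 7.5e-06, and -2.38 as deposited). APTX (AT5G01310), an aprataxin-like gene of DNA repair, fell by 2.52 ± 0.45 (adjusted p = 0.0011, and 0.060 with number pairs averaged). The chromatin remodelling gene chr31 (AT1G05490) fell by 2.04 ± 0.14 (adjusted p = 1.7e-06). AT4G22830 went from 67.5 ± 6.55 to 16.0 ± 2.09 (-1.69 ± 0.12, adjusted p = 2.3e-06, and -3.17 with median centring). AT1G11730, which encodes a galactosyltransferase, fell by 1.69 ± 0.16 (adjusted p = 1.7e-05, and -0.74 as deposited). AT3G56010 fell by 1.87 ± 0.25 (adjusted p = 1.8e-04, and -1.02 as deposited), with 3 sucrose arrays at the floor. AT4G27510, AT1G24040 and AT3G06870 did not pass with the values as deposited. AT4G27510 fell by 1.89 ± 0.37 (adjusted p = 0.0019, and -0.89 with 0.077 as deposited). AT1G24040, which encodes a GNAT-type acetyltransferase, fell by 1.82 ± 0.36 (adjusted p = 0.0021, and -0.87 with 0.15 as deposited), with 2 sucrose arrays at the floor. AT3G06870 fell by 1.64 ± 0.33 (adjusted p = 0.0023, and -0.55 with 0.22 as deposited), with 1 sucrose array at the floor, within numbers 5 and 6 its difference was -0.41 (adjusted p = 0.55), and without numbers 1 and 2 it had adjusted p = 0.061. With number pairs averaged, 8 of the 10 rises and 6 of the 10 falls passed, without APTX, AT4G27510, AT1G24040 and AT3G06870. All 10 rises and all 10 falls had the same sign within each of the 3 number pairs, as had 1399 of the 1436 called probes (97.4%). The genes were picked for their differences on these same arrays, so the shared sign is no separate support.

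**Figure D2:**
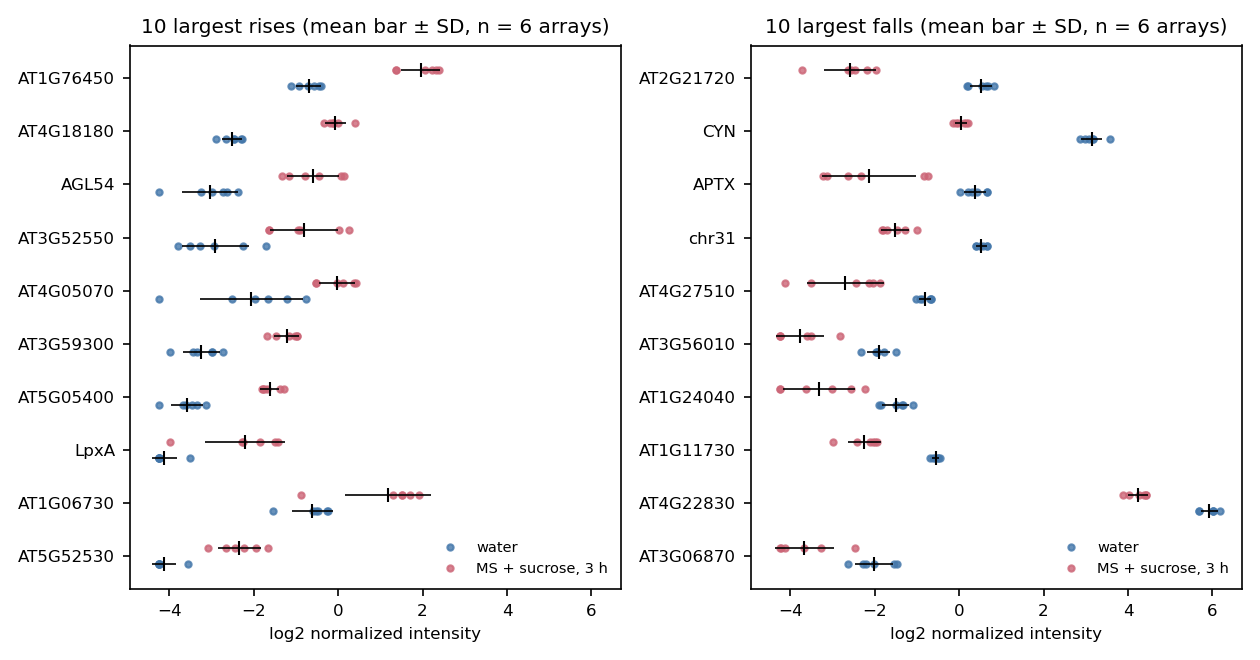
Log2 normalized intensity of the 10 largest rises (left) and the 10 largest falls (right) among genes with a probe of their own. Each of 6 water (blue) and 6 sucrose (red) arrays is a point, with a tick at the group mean and a line for its SD. The points furthest left are at the floor of -4.23. The groups lie apart for most genes, while array 3 of AT1G06730 lies low in both, and the falls of AT4G27510, AT1G24040 and AT3G06870 did not pass as deposited, nor the rise of AT1G06730 with median centring.

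Of the 18 gene lists fixed before the data were examined, 5 had any gene with a probe of its own, 9 genes in all out of 321. In the list of light harvesting and photosystem subunits, 1 of 4 measured genes passed the threshold, 1 also when adjusted over the list alone. PSBW (AT2G30570), a small subunit of photosystem II, was called higher in sucrose after quantile normalization by 0.61 ± 0.14 (log2, adjusted p = 0.0053), but its deposited intensity was 44.3 ± 3.21 in water and 45.9 ± 5.01 in sucrose (0.05, adjusted p = 0.66) and with median centring it was called lower at -1.05 (adjusted p = 1.3e-05). The others did not pass after quantile normalization. PSAN (AT5G64040), a subunit of photosystem I, differed by 0.29 ± 0.12 (adjusted p = 0.067), PSBY (AT1G67740), of photosystem II, by -0.20 ± 0.11 (adjusted p = 0.19) and the light-harvesting gene LHB1B2 (AT2G34420) by 0.14 ± 0.12 (adjusted p = 0.42), whereas with median centring all of them passed as lower, at -0.90 (adjusted p = 0.0053), -1.08 (6.4e-04) and -1.18 (0.0024). PSAN passed as higher with cyclic loess, at 0.33 (adjusted p = 0.032), and without sucrose array 3, at 0.35 (adjusted p = 0.031). With number pairs averaged, PSBW had adjusted p = 0.11.

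In the Calvin cycle list, 1 of 2 measured genes passed, 1 also when adjusted over the list alone. PRK (AT1G32060), which encodes phosphoribulokinase, went from 1.93 ± 0.409 to 2.94 ± 0.736 (SD, n = 6 each), higher by 0.61 ± 0.15 (adjusted p = 0.0076) and by 0.60 as deposited (adjusted p = 0.014), but at -0.50 with median centring and with adjusted p = 0.13 both when number pairs were averaged and without numbers 1 and 2. The other gene, SBPASE (sedoheptulose bisphosphatase, AT3G55800), was listed at 0 on all 12 arrays.

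In each of 3 more lists 1 gene was measured, and none passed. ETFQO (AT2G43400), of the sugar starvation and dark-induced list, which takes electrons from branched-chain amino acid breakdown, differed by -0.28 ± 0.28 (adjusted p = 0.49) and by 0.84 as deposited. PPDK (AT4G15530), pyruvate orthophosphate dikinase of the glycolysis and organic acid list, differed by -0.10 ± 0.16 (adjusted p = 0.72), whereas as deposited it went from 0.278 ± 0.0449 to 0.518 ± 0.116 (0.88, adjusted p = 7.6e-04). AT4G17260, the lactate dehydrogenase of the low oxygen list, was at the floor on all 12 arrays. The other 13 lists had no gene with a probe of its own: nitrate uptake and assimilation, starch and sucrose metabolism, phenylpropanoids and flavonoids, phosphate starvation, sulfate assimilation, proline with osmotic and cold stress, aquaporins, touch and wounding with jasmonate and defence, heat shock, the circadian clock, markers of root, seed and flower, cytosolic ribosomal proteins and the proteasome. No list reached the 5 measured genes set for a test of the whole list, so none was run.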

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

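Among the 58 sets of 6 arrays searched, 54 of a named gene in a group and 4 of array medians and shares at 0, 5 had an array whose gap to the nearest other array exceeded 0.625 of the whole range. In the 53 sets with at most 1 array at the floor there were 3 such arrays, and chance alone sets apart about 1 set in 20. AT1G06730, the pfkB-type carbohydrate kinase gene, stood out in both groups at the same array number. Water array 3 had a log2 value of -1.54 against -0.60 to -0.24 on the other 5 (gap 0.722 of the range), and sucrose array 3 had -0.87 against 1.31 to 1.91 (0.781). For LpxA, sucrose array 4 had -3.99 against -2.28 to -1.42 (0.663). In the remaining 2 sets the gap is the whole range (1) by construction, since the other 5 water arrays were at the floor of -4.23: LpxA had -3.51 on water array 6 and AT5G52530 had -3.56 on water array 2.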

How the results depend on the processing

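Fits with number pairs as a random block, averaged or each alone, without numbers 1 and 2, or with 0.2 added were chosen after seeing the data, as were the pairs themselves and their block for single genes. The count of 1436 called probes stayed within 1.5 times under every alternative chosen beforehand (997 at an adjusted p of 0.01 to 2075 as deposited), and between 1323 and 1470 with any 1 array left out. With the replicate block it was 1383, 1278 of them shared, and the block changed no call of a named gene. Its adjusted p-values were larger than those of the main fit for all called genes but AT1G06730 (0.0023 against 0.0083). CYN had 1.1e-04 with the block, AT4G18180 1.3e-04, PSBW 0.021, AT3G06870 0.025, AT3G52550 0.033 and AT4G05070 0.034. The count was 1591 with number pairs as a block, 1214 without numbers 1 and 2, 1116 with number pairs as a random block, 730 with number pairs averaged (3 against 3), 1114 within numbers 1 and 2, 750 within numbers 3 and 4, and 674 within numbers 5 and 6. Of 780 values of named genes under alternatives, 722 kept direction and side of the threshold, 41 lost the threshold, 4 gained it and 13 reversed. These counts leave size aside. Adding 50, large on a scale that ends at 100, took AGL54 from 2.44 to 0.02 and AT2G21720 from -3.1 to -0.04. Adding 0.2 took the dim gene AT5G05400 from 1.96 to 0.88, but the brighter CYN only from -3.1 to -2.87. No call was lost when 1 array was left out (324 values). Of the 22 called genes 2 reversed, both with median centring, PSBW to -1.05 and PRK to -0.50. The other reversals were of genes not called: with median centring PSAN to -0.90 and LHB1B2 to -1.18, as deposited ETFQO to 0.84, PPDK to 0.88, LHB1B2 to -0.09 and PSBY to 0.01, within numbers 1 and 2 ETFQO to 0.12, within 3 and 4 PSAN to -0.02 and LHB1B2 to -0.13, and within 5 and 6 PPDK to 0.13 and PSBY to 0.05. The cause was not tested. The list test and its alternatives were not run, as no list had 5 measured genes. Intensity near the floor limits the dim genes.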

Other observations

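The gene groups in this part were drawn up after the gene names and values were seen, and the tests of background, range and array numbers were chosen after their results were seen. The counts of splits were planned, but the averaging of number pairs that one of them uses was chosen after seeing the data. Of 15 measured genes of the photosynthetic complexes and their assembly, 4 were called higher, 3 lower and 8 did not pass after quantile normalization, and no shift against the other genes passed (camera over 691 genes, adjusted p = 0.78, and adjusted p = 0.82 with an estimated correlation). NdhN and AT1G49380, counted among those that did not pass, were at the floor on all 12 arrays and could show no change. The median of the group was 0 and its mean 0.22. As deposited its median was 0.19 against 0.74 over all 691 genes (adjusted p = 0.56), and with median centring -0.82 against 0 (adjusted p = 0.78). The calls were 5 higher and 1 lower as deposited, 3 higher and 8 lower with median centring, and 3 higher and 1 lower with number pairs averaged. AT1G54500, for a rubredoxin, was called lower (-0.24, adjusted p = 0.024) but higher as deposited (0.48, adjusted p = 1.8e-05). With median centring it was called lower too (-0.62, adjusted p = 3.9e-04). It did not pass with number pairs averaged (adjusted p = 0.18) or cyclic loess (adjusted p = 0.12). None of the 4 groups large enough for camera passed under any of the 4 scalings. PIFI, which works with the chloroplast NDH complex, went from 0.402 ± 0.0294 to 1.15 ± 0.099 (SD, n = 6 each; log2 0.90 ± 0.07, adjusted p = 5.9e-06), and AT1G74730, which encodes a thylakoid grana protein, rose by 1.72 ± 0.35 (adjusted p = 0.0027, with 1 water array at the floor). Both were higher under all 4 scalings. AT1G22700, a photosystem I assembly gene, was called lower by -0.79 ± 0.14 (adjusted p = 0.0012) and LPA19, a photosystem II assembly gene, by -1.06 ± 0.32 (adjusted p = 0.021, and 0.094 with number pairs averaged), but as deposited they stood at 0.28 and 0.04. Of 5 plastid ribosomal protein genes 2 were called higher and 1 lower (camera adjusted p = 0.78, and adjusted p = 0.82 with an estimated correlation), against 4 and 0 as deposited, 0 and 1 with median centring, and 1 and 0 with number pairs averaged. AT1G64510, for S6, was at the floor on all 12 arrays. AT5G65220, for protein L29, went from 1.94 ± 0.263 to 6.32 ± 1.38 (log2 1.75 ± 0.10, adjusted p = 4.9e-07) but did not pass with median centring (0.58, adjusted p = 0.090), while AT3G13120, for S10, was at -0.63 ± 0.20 (adjusted p = 0.024, and 0.079 with number pairs averaged) but called higher as deposited (0.61, adjusted p = 0.043). The other gene called higher, AT4G01310 for L5 (0.48 ± 0.17, adjusted p = 0.043), did not pass with median centring (adjusted p = 0.36) or number pairs averaged (adjusted p = 0.15).

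Of 5 genes of tetrapyrrole and isoprenoid synthesis 2 were higher and 1 lower (camera adjusted p = 0.78, and adjusted p = 0.85 with an estimated correlation), with a median of -0.20 but a mean of 0.07, the sign that camera gave. The calls were 3 higher and 0 lower as deposited, 1 and 1 with median centring, and 1 and 0 with number pairs averaged, where SIRB (0.54 ± 0.20, adjusted p = 0.050 after quantile normalization) had adjusted p = 0.22. AT1G74470, the geranylgeranyl reductase of chlorophyll and tocopherol synthesis, went from 1.78 ± 0.147 to 3.26 ± 0.388 (log2 0.93 ± 0.11, adjusted p = 7.1e-05) but stood at -0.22 with median centring. Of 5 cell wall genes 1 was called higher and 2 lower (camera adjusted p = 0.78, and adjusted p = 0.82 with an estimated correlation), against 3 and 0 as deposited, where GH9B11 (0.74, adjusted p = 0.014) and GH9B16 (1.19, adjusted p = 1.8e-04) were called higher too. Within the glycosyl hydrolase family 9B, GH9B8 rose by 1.15 ± 0.25 (adjusted p = 0.0038, with 5 water arrays at the floor) and GH9B12 fell (-1.60 ± 0.20, adjusted p = 9.7e-05), and the mannan synthase family gene CSLA01 fell by 1.53 ± 0.19 (adjusted p = 1.1e-04, with 2 sucrose arrays at the floor). GH9B8 passed under all 4 scalings, but with 5 water arrays at the floor, the floor sets the size of its rise. As deposited GH9B12 was at -0.53 (adjusted p = 0.13) and CSLA01 at -0.39 (adjusted p = 0.23). Of 3 histone H3 genes AT5G65360 rose by 1.09 ± 0.16 (adjusted p = 3.5e-04), and as deposited all 3 were called higher. Of 4 plastid fibrillin genes AT2G46910 rose by 1.12 ± 0.41 (adjusted p = 0.048, with 3 water arrays at the floor) and AT2G35490 was lower at -0.54 ± 0.18 (adjusted p = 0.032), but at 0.54 as deposited. With number pairs averaged these had adjusted p = 0.22 and 0.15, and as deposited 3 of the 4 were called higher and 0 lower. AT4G31530 was at the top of the scale on all 6 water arrays and at 73.5 ± 12.5 on the sucrose arrays. It was saturated in water, so no fold is given.

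The calls as deposited ran mostly one way, 1848 higher and 227 lower in sucrose, and the shift depended on level. In groups of probes formed by their level in water, medians of 0.0774, 0.141, 0.269 and 0.54 in water went with 0.23, 0.338, 0.514 and 0.747 in sucrose, whereas 1.1 went with 1.1 and 29.9 with 22.2. A background added to the sucrose arrays could give gains of dim groups. An equal amount on every probe would not by itself give the dimmest group a smaller rise in intensity than the groups next to it. Processing that sets dim values to 0 could lessen that rise. Whether it could go with the loss of the bright ones depends on how the arrays were scaled, which the sources do not give. Added background stays open. Of the sucrose values of the 301 probes at 0 on all 6 water arrays 78.5% were also 0. But 123 of these probes were at 0 on all 12 arrays, where processing may have set the 0. A compressed intensity range stays open too, since the log-log slopes of a sucrose array on the water array of its number reached 0.863 at most, below the 0.964 to 1.04 between water arrays, and were lower for numbers 1 and 2 (0.767 and 0.731). A treatment response that raised many weak transcripts and lowered strong ones may give the same values, so the 3 cannot be told apart, since all sucrose arrays share the treatment.

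The array numbers carry a structure that the labels do not describe. Pairing 1 with 2, 3 with 4 and 5 with 6 gave the highest mean correlation of deviations of all 15 pairings in both groups (rank 1), 0.19 against -0.039 for the next in water and 0.34 against 0.13 in sucrose. The difference of odd minus even numbers also correlated between different pairs, with a mean of 0.076 over 12 correlations, above the highest of the other sign assignments at 0.041 (1 of 32, p = 0.031, the smallest they can give). No biological explanation was tested. Consecutive numbers may be repeats of the same RNA or preparation, with odd and even numbers as separate spot sets or positions. In that case the arrays are closer to 3 samples per group.

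Of 100 splits of the 12 arrays into 6 and 6, 1 gave as many called probes, the real split with 1436, and the highest other gave 2. This would count against chance only if the 12 arrays could be exchanged freely. Of the 32 splits that part all same-numbered arrays, 1 gave as many with the replicate block, the real split with 1383, and the highest other gave 1. The resemblance of consecutive numbers goes against free exchange in both of these counts, so neither of them excludes chance. Averaging number pairs allows for this resemblance within a group, but not for the likeness of same-numbered arrays between groups. With the pairs averaged, the 10 splits of 3 against 3 are too few for a share under 0.05. The real split gave 730 probes there and the highest other 1.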
